A study of Mus musculus with 6 samples.

How the data were processed

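Single-cell RNA sequencing of Lin- haematopoietic stem and progenitor cells was available from 6 mice, 3 with a Stag2 knockout and 3 wild type. Libraries were made from polyadenylated RNA with the 10x Chromium Single Cell 3' version 2 chemistry, per the labels. The labels gave the genotype of each sample, and the series design text counted 3 mice in each group. Sample numbers follow accession order and pair nothing. Titles carried a code whose prefix was XA in the 3 knockout samples and WT1 and differed in WT2 and in WT3; what the prefix marks is not given in the sources used here.

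The authors deposited, for each sample, a table of whole-number UMI counts per cell and gene, not normalized, with a cluster number per cell that was used here only for a comparison of groupings (adjusted Rand index 0.388 to 0.496 within samples). The aligner, the counter and the genome build behind these counts are not given in the sources used here. No deposited cell exceeded 20% mitochondrial counts, and that filter therefore removed none here. The tables held 15930, 15294 and 15527 genes in KO1, KO2 and KO3 and 15379, 15942 and 16181 in WT1, WT2 and WT3. Of 18011 gene symbols in any sample 13876 were in every sample, and a gene missing from a sample was set to 0 there; the highest such gene reached 6.76 CPM in another sample. Repeated symbols were summed (6 to 8 per table). Symbols were matched to GENCODE release M21 (GRCm38), which placed 17437 of them and gave the coordinates; the build behind the counts may differ.

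Cells with at least 500 genes and at most 20% mitochondrial counts were kept. A simulated-doublet score removed the highest-scoring cells at 0.8% per 1000 cells, which were 160, 47 and 113 cells in KO1, KO2 and KO3 and 48, 156 and 367 in WT1, WT2 and WT3. The kept cells had a median of 5941, 5731 and 5916 UMIs in the knockout samples and 4294.5, 4889.5 and 3485 in the wild type samples. Cells of all samples were clustered together with no integration, from 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0, which gave 32 clusters (21 at 0.5 and 46 at 2.0). A marker, fixed beforehand, counted as raised at 2-fold or more above the other clusters and at 20 CPM or more. A cluster took the name of the cell type with the largest share of its markers raised, at least 3 markers and at least 1 in 3 of the type's list. Where its leading genes held more markers of another type, it took that name if that type met the same bounds. Otherwise, or in a tie, it was left unnamed. Its leading genes were the top 10 by fold among genes at 50 CPM or more, with 5 CPM added. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1, with random seed 1.

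Raw counts were summed per sample over all kept cells and over each of the 9 classes with at least 20 cells in every sample. Class sums ranged from 222600 UMIs (WT1, megakaryocyte) to 7394254 (KO1, granulocyte progenitor). The sums were tested with edgeR's quasi-likelihood test (TMM factors, low-count filter, Benjamini-Hochberg adjustment at 0.05). Gene lists were tested with camera in limma at a preset correlation of 0.01, with an estimated correlation as an alternative; 28 lists were fixed, 16 of cell types and 12 others, and a list needed 5 tested members. Shares of cells were compared with a 2-sided exact permutation test over the 20 assignments of 3 and 3 samples, with 95% exact binomial intervals per sample. Such intervals, and the floor of 3 counts, cover counting error only. Differences between classes were tested with limma on each sample's difference between a class and the mean of the others, over 4881 genes, a test chosen after the data were seen.

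Samples, tests, gene lists, markers, the rule for named genes and 26 alternatives were chosen before the data were examined. The rule took genes past 0.05 whose genotypes did not overlap and with a mean of at least 10 CPM, the 12 with the largest change in each direction over all cells and 5 in each class. Up to 4 list members with the smallest p were added, as were Stag2, Stag1, Ebf1, Pax5, Spi1, Gata1, Klf1, Cebpa, Irf8 and Hoxa9. List members with larger p, and Mcpt8 and Ifitm1 levels set between classes, were chosen after their values were seen. Predicted genes were counted but not named, and sex-linked genes were set apart. Within classes the text describes mainly lists that kept their calls without each library and with the prefix covariate, and each class's own markers. The alternatives were DESeq2, RLE factors, no low-count filter, the prefix as a covariate, no cell filter, each library left out, the same class shares in every sample, other resolutions, doublets kept, cells with at least 2000 UMIs, classes from marker scores, edgeR on cell counts and the XA samples alone.

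The edgeR step was tested on simulated counts with 200 genes changed. Over all cells (12646 genes) it recovered 87% of genes changed 2-fold and 99% changed 4-fold, with 10.1% false among its calls. In classes it recovered 69% (lymphoid progenitor, 6278 genes) to 87% (HSC/MPP, 9617 genes) of 2-fold changes. The limma step, simulated for HSC/MPP over 4881 genes, recovered 100% of 4-fold changes with 5.21% false. Libraries of a genotype differed by more than counting noise (chi-square over degrees of freedom 15.1 to 36.9), so none was counted as a repeat of another. On the first principal component of the sums, with 58.1% of the variance, the genotypes lay apart.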

Results

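Cells without the surface markers of mature blood lineages (lineage-negative, Lin-), the fraction that holds haematopoietic stem and progenitor cells, were profiled from 3 mice with a Stag2 knockout (KO1, KO2 and KO3) and 3 wild type mice (WT1, WT2 and WT3). Stag2 encodes a subunit of cohesin, the ring-shaped complex that holds sister chromatids together and shapes chromatin loops, and Stag1 encodes the subunit that can take its place. The design sets the genotypes against each other to ask how loss of Stag2 alters which blood cells form and what they express. The deposited tables held 4635, 2604 and 3817 cells with 36248233, 20131867 and 30224256 unique molecular identifiers (UMIs) for KO1, KO2 and KO3. They held 2783, 4744 and 7053 cells with 16155065, 31344078 and 35347688 UMIs for WT1, WT2 and WT3. The median UMI count per deposited cell was 5797, 5458 and 5956 in the knockout samples and 3731, 4613 and 3447 in the wild type samples. After filtering, 4315, 2385 and 3639 knockout cells and 2412, 4258 and 6407 wild type cells were kept. Genes of the Y chromosome were expressed in all 6 samples.

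Stag2, the targeted gene, fell in the knockout samples but was not lost from the counts. Its level over all kept cells was 24.7, 23.5 and 19.9 CPM (counts scaled to a common total per sample) in KO1, KO2 and KO3, against 54.6, 42.6 and 43.7 CPM in WT1, WT2 and WT3. The log2 fold change was -1.04 ± 0.11 (SE, edgeR adjusted p = 5.61e-04). Stag2 lies on chromosome X at 42149317 to 42277185 on the plus strand of GRCm38, and the labels do not say which part of it was deleted. The library reads the 3' end of transcripts, so a tag may lie outside the deleted part, and the remaining counts do not measure intact transcript. Within cell classes, Stag2 fell in HSC/MPP (-0.85), T/NK cell (-0.86), basophil/mast cell (-1.39), early erythroid (-0.80), granulocyte progenitor (-0.86) and monocyte (-1.37) classes on the log2 scale, with edgeR adjusted p between 1.22e-05 and 0.0110. It did not pass in dendritic cells (-0.61, edgeR adjusted p = 0.161), lymphoid progenitors (-0.37, 0.531) or megakaryocytes (-0.82, 0.385). Stag1 (chromosome 9, 100597798 to 100959375, plus strand) rose from 33.6 ± 1.93 to 41.6 ± 2.68 CPM (SD, n = 3 each), a log2 fold change of 0.31 ± 0.08 (edgeR adjusted p = 0.0297). The Stag1 call ended with the prefix of the sample titles as a covariate (0.22, edgeR adjusted p = 0.301). It also ended without KO1 (adjusted p = 0.0667), KO2 (0.0918), KO3 (0.0668), WT2 (0.126) and WT3 (0.0763) in edgeR.

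The makeup of the Lin- fraction differed between the genotypes. B cell-like cells were 0.0878% ± 0.0205 (SD, n = 3) of the kept knockout cells and 1.89% ± 0.411 of the wild type cells, a 21.5-fold lower share. They numbered 3, 2 and 4 cells in KO1, KO2 and KO3 against 57, 69 and 108 in WT1, WT2 and WT3, and the share in KO1 has an exact 95% binomial interval of 0.0143% to 0.203%. T/NK cell-like cells were 9.84% ± 3.28 of knockout and 17.3% ± 2.27 of wild type cells, and lymphoid progenitor-like cells 2.62% ± 0.256 and 3.97% ± 0.639. The neutrophil branch went the other way: granulocyte progenitor-like cells were 9.63% ± 2.0 and 3.85% ± 2.24, and late neutrophil-like cells 1.51% ± 0.373 and 0.200% ± 0.138. Megakaryocyte-like cells were 3.14% ± 0.217 of knockout and 1.33% ± 0.340 of wild type cells, and HSC/MPP-like cells (haematopoietic stem cells and multipotent progenitors) 11.9% ± 2.48 and 7.86% ± 0.486. Dendritic cell-like cells were 9.27% ± 1.74 and 7.15% ± 1.38.

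Each class name stands for cells like that type by the fixed markers. In these 8 classes no knockout sample overlapped a wild type sample, yet the 2-sided exact permutation test of 3 against 3 cannot go below p = 0.1, which is the value it gave (Benjamini-Hochberg adjusted p = 0.163 over 13 tests). Basophil/mast cell-like (25.1% ± 2.78 and 26.3% ± 2.05, exact p = 0.7), early erythroid-like (6.24% ± 0.807 and 6.04% ± 0.362, exact p = 0.9) and monocyte-like cells (6.40% ± 2.20 and 9.44% ± 1.41, exact p = 0.3) overlapped between genotypes. So did eosinophil-like cells (0.545% ± 0.348 and 0.258% ± 0.0610, exact p = 0.3) and cells left unnamed (13.8% ± 0.253 and 14.4% ± 1.22, exact p = 0.7). edgeR on the cell counts, an alternative test, put B cell (log2 fold change -4.37), late neutrophil (2.72), megakaryocyte (1.22), granulocyte progenitor (1.29), HSC/MPP (0.60), T/NK cell (-0.82) and lymphoid progenitor (-0.59) shares past its threshold, with adjusted p from 7.39e-06 to 0.0292. Shares are of cells that passed lineage depletion, so they can reflect that step.

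**Figure D1:**
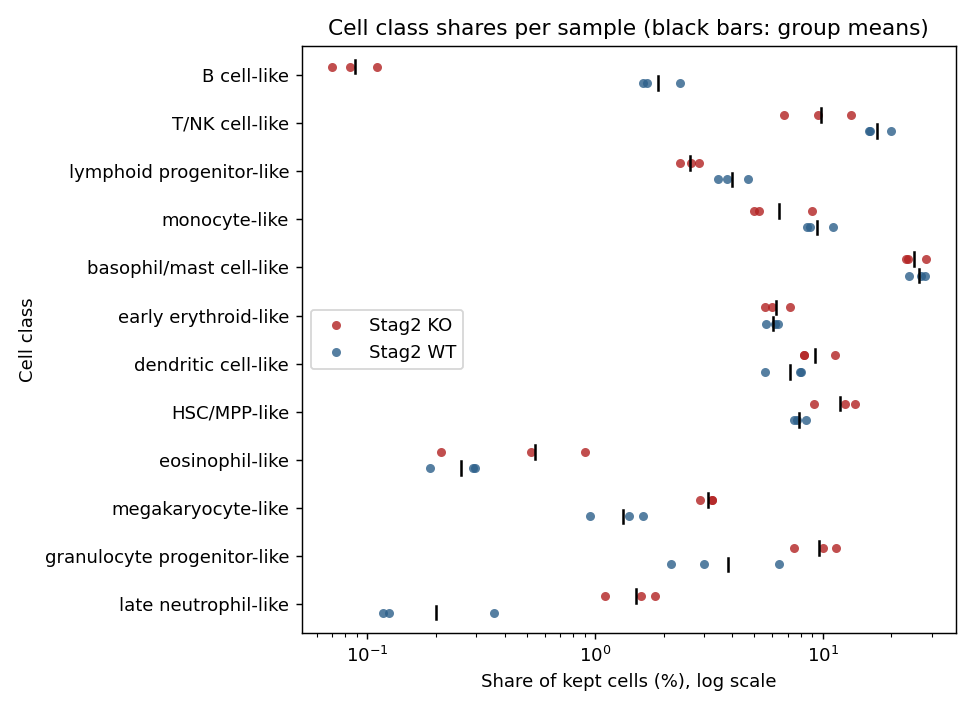
Share of kept cells in each named class, in percent on a log axis, with a point per sample (red knockout, blue wild type, n = 3 each) and a black bar at each group mean. The knockout points lie below all wild type points in the B cell-like, T/NK cell-like and lymphoid progenitor-like classes and above them in the late neutrophil-like, granulocyte progenitor-like and megakaryocyte-like classes.

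Over all kept cells, genes of neutrophil granules were among the largest rises in the knockout samples. Chil3, a chitinase-like protein of myeloid cells, rose from 18.5 ± 14.8 to 173 ± 75.4 CPM (SD, n = 3 each), a log2 fold change of 3.20 ± 0.50 (edgeR adjusted p = 0.00293). Camp, the cathelicidin antimicrobial peptide, rose from 153 ± 97.8 to 987 ± 337 CPM (2.68 ± 0.41, edgeR adjusted p = 0.00290). Ngp, a protein of neutrophil granules, rose by 2.80 on the log2 scale, and Fcnb, the lectin ficolin B, by 2.51. S100a9 (2.36) and S100a8 (1.80), the subunits of calprotectin, Lcn2 (2.32), the siderophore-binding lipocalin, and Wfdc21 (2.11), a WAP domain protein, rose as well. Trem3 (1.4), a receptor of myeloid cells, Prss57 (1.21), a serine protease of neutrophil granules, Pde4d (1.28), a phosphodiesterase that degrades cyclic AMP, and Dmkn (1.24), the secreted protein dermokine, completed the genes with the largest rises. For these 12 genes edgeR adjusted p ran from 6.73e-04 to 0.0213. Camp lies on chromosome 9 at 109847379 to 109849617 (minus strand of GRCm38) and Chil3 on chromosome 3 at 106147554 to 106167564 (minus strand).

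Genes of B cells were among the largest falls. Vpreb3, which takes part in assembly of the pre-B cell receptor, fell from 41.9 ± 10.6 to 1.31 ± 1.24 CPM (log2 fold change -4.89 ± 0.39, edgeR adjusted p = 1.24e-04). Ebf1 (chromosome 11, 44617317 to 45008091, plus strand), a transcription factor that commits progenitors to the B lineage, fell from 43.9 ± 15.3 to 2.26 ± 1.02 CPM (-4.21 ± 0.30, edgeR adjusted p = 5.88e-05). Cd79a (-3.96), a signalling chain of the B cell receptor, and Pax5 (-3.17, 0.143 against 1.36 CPM), which maintains B cell identity, fell with them. Ifitm1 (chromosome 7, 140967221 to 140969825, plus strand), an interferon-inducible membrane protein, fell from 831 ± 43.7 to 115 ± 17.3 CPM (-2.85 ± 0.11, edgeR adjusted p = 1.20e-06). Igfbp7 (-4.03), which binds insulin-like growth factors, Cnn3 (-3.71), the actin-binding calponin 3, Cdh1 (-2.70), E-cadherin, and Mt2 (-2.60), a metallothionein, also fell. Cd8b1 (-2.32), a chain of the CD8 coreceptor, and C5ar1 (-2.28), the receptor of complement fragment C5a, fell, as did Hist1h2ap (-2.30), a replication-dependent histone, and Hba-a1 (-2.21), alpha globin. The last 2 have near-identical copies in the genome, so their counts are uncertain. For these 13 genes edgeR adjusted p lay between 1.60e-07 and 0.00972.

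Of the transcription factors reported in any case, Klf1, which drives erythroid genes, fell (-0.74 ± 0.13, 14.4 against 24.1 CPM, edgeR adjusted p = 0.00484), and Irf8, a factor of monocytes and dendritic cells, fell (-0.47 ± 0.13, 353 against 488 CPM, edgeR adjusted p = 0.0429). Spi1, the myeloid and B cell factor PU.1, stood at 238 ± 6.23 and 239 ± 3.84 CPM (-0.01, edgeR adjusted p = 0.960). Gata1 (-0.23, 0.159), the erythroid and megakaryocyte factor, Cebpa (0.38, 0.15), a factor of granulocyte and monocyte progenitors, and Hoxa9 (-0.04, 0.866), a stem and progenitor cell factor, did not pass in edgeR either.

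In all, 1360 of 12646 tested genes passed in edgeR, 462 higher and 898 lower in the knockout samples. In 1354 of them the genotypes did not overlap, and 29.8% of all tested genes did not overlap where chance gives 10%. With counts reweighted to the same class shares in every sample, Camp (0.05, edgeR adjusted p = 0.839), Ngp (0.20, 0.608), Vpreb3 (-1.20, 0.119) and Ebf1 (-0.92, 0.179) no longer passed. That scales up 3, 2 and 4 knockout B cells, and 3 and 5 late neutrophils of WT1 and WT2, so it rests on few cells. S100a9 (-0.07, 0.833) and S100a8 (-0.15, 0.386) turned downward without passing. The same weights moved Chil3 to 1.48, Lcn2 to 1.09, Fcnb to 0.78, Pde4d to 0.69, Wfdc21 to 0.56, Prss57 to 0.55, Trem3 to 0.44, Dmkn to 0.39, Cd8b1 to -1.48 and Cd79a to -0.48 on the log2 scale. The title code prefix as a covariate left 754 genes past 0.05, 653 of them shared, and moved Hist1h2ap to -1.22, while edgeR called 748 genes without KO1, 831 without KO3 and 811 without WT2. S100a8 also lost its call with DESeq2 (adjusted p = 0.0607), and in edgeR without KO1 (0.0697) or WT2 (0.0746). Vpreb3 stood at -5.84 without KO3, Hba-a1 at -1.56 without WT1 and Chil3 at 4.13, Ngp at 3.62, Camp at 3.34, Fcnb at 3.38, Wfdc21 at 2.70 and S100a8 at 2.64 without WT3 (log2 scale).

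**Figure D2:**
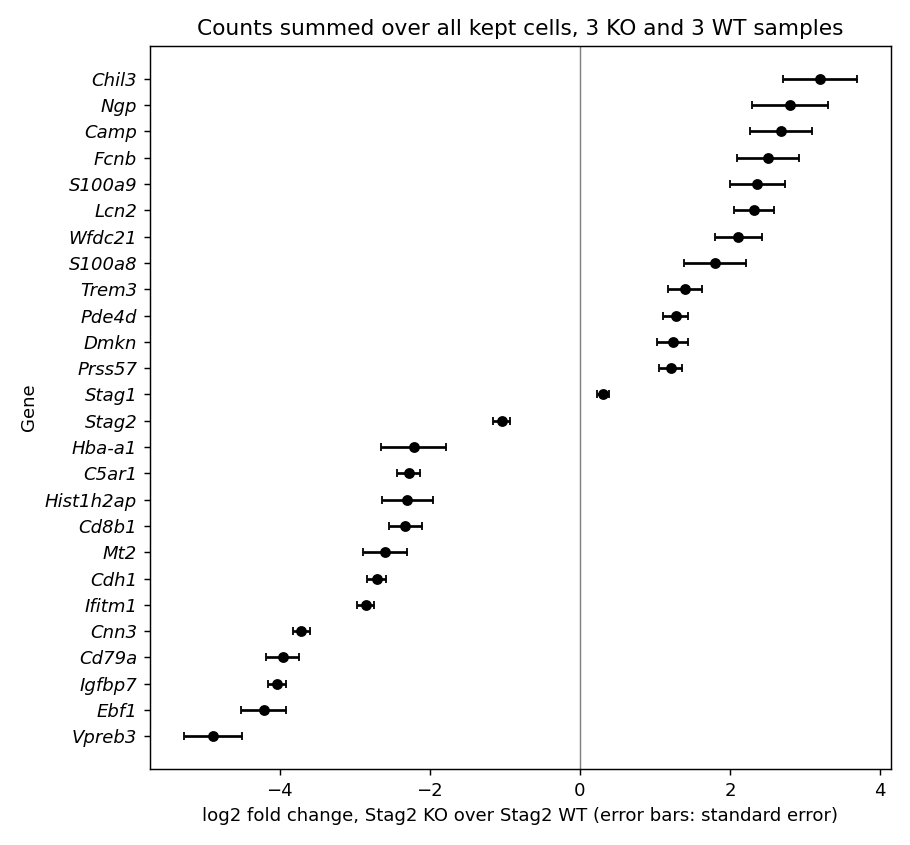
Log2 fold change of the named genes, Stag2 knockout over wild type, from counts summed over all kept cells of each sample (edgeR, n = 3 each), with standard errors as bars. Values run from 3.20 for Chil3 to -4.89 for Vpreb3.

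The fixed lists of cell type markers were tested with limma's camera on the edgeR fit of all cells. The B cell list fell (limma camera, adjusted p = 8.39e-34, 0.125 with estimated correlation). Of the 15 members 12 fell over all genes and 13 adjusted over the list alone, with Ms4a1 (-5.54), Pou2af1 (-4.24) and Igll1 (-2.18) on the log2 scale. Ms4a1 encodes the B cell surface protein CD20. The lymphoid progenitor list fell (limma camera, adjusted p = 8.13e-09, 0.125 with estimated correlation). Of the 12 members 6 fell over all genes and 9 adjusted over the list alone, among them Rag1 (-2.37), Dntt (-1.09), Flt3 (-1.0) and Il7r (-0.75). Rag1 and Dntt act in antigen receptor recombination, and Flt3 and Il7r are cytokine receptors of early lymphoid cells. The T/NK cell list fell (limma camera, adjusted p = 3.37e-09, 0.194 with estimated correlation). Of the 13 members 8 fell over all genes and 11 adjusted over the list alone, among them the CD3 chains Cd3d (-1.85), Cd3g (-1.83) and Cd3e (-1.82). The granulocyte progenitor list rose (limma camera, adjusted p = 2.60e-10, 0.194 with estimated correlation). Of the 12 members 8 rose over all genes and 10 adjusted over the list alone, among them Cebpe (1.19), Gstm1 (1.12), Prtn3 (0.98) and Mpo (0.71). Cebpe is a transcription factor of granulocyte maturation, and Prtn3 and Mpo are enzymes of primary granules. The late neutrophil list rose (limma camera, adjusted p = 8.13e-09, 0.194 with estimated correlation): of 13 members 8 rose and 0 fell over all genes, and 9 and 2 adjusted over the list alone, with Cd177 (2.01) beside the granule genes above.

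The megakaryocyte list rose (limma camera, adjusted p = 3.16e-09, 0.17 with estimated correlation): of 15 members 9 rose and 1 fell over all genes, and 11 and 1 adjusted over the list alone, among them Serpine2 (1.12), Gp5 (1.03), Gp9 (0.99) and Itga2b (0.33), while Vwf (-0.73), von Willebrand factor, fell. Gp5, Gp9 and Itga2b are platelet receptor subunits. The early erythroid list fell (limma camera, adjusted p = 5.48e-13, 0.194 with estimated correlation): of 18 members 1 rose and 13 fell over all genes, and 2 and 14 adjusted over the list alone, among them Rhd (-2.23), Atp1b2 (-2.08), Aqp1 (-1.32) and Epor (-0.74), the last of these the erythropoietin receptor, while the mucin Muc13 (0.46) rose. The late erythroid list fell (limma camera, adjusted p = 0.0323, 0.596 with estimated correlation). Of the 16 members 5 fell over all genes and 5 adjusted over the list alone, with Trim10 (-2.44), Hbb-bs (-1.56) and Hbb-bt (-0.79) beside Hba-a1, and its call ended without KO2 (adjusted p = 0.261) and without WT1 (adjusted p = 0.0816). The monocyte list fell (limma camera, adjusted p = 5.12e-10, 0.194 with estimated correlation). Of the 14 members 6 fell over all genes and 10 adjusted over the list alone, with Slpi (-1.94), Ms4a6c (-1.27), Cx3cr1 (-0.90) and Csf1r (-0.78). The dendritic cell list fell (limma camera, adjusted p = 3.78e-05, 0.323 with estimated correlation). Of the 13 members 7 fell over all genes and 9 adjusted over the list alone, with Batf3 (-1.55), Cox6a2 (-1.50) and Cd209a (-0.91). The basophil/mast cell list fell (limma camera, adjusted p = 2.49e-05, 0.194 with estimated correlation): of 12 members 1 rose and 5 fell over all genes, and 1 and 7 adjusted over the list alone, with Fcer1a (-1.46), Mcpt8 (-1.20) and Prss34 (-0.84), genes of the high-affinity IgE receptor and of basophil proteases, while Il1rl1 (0.77), the receptor of interleukin 33, rose.

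The plasma cell list fell (limma camera, adjusted p = 0.00155, 0.194 with estimated correlation). Of the 9 members 4 fell over all genes and 5 adjusted over the list alone, with Igha (-1.58), Sdc1 (-1.26), Igkc (-1.25) and Jchain (-1.23). The macrophage list fell (limma camera, adjusted p = 0.0139, 0.194 with estimated correlation): of 8 members 1 rose and 3 fell over all genes, and 1 and 5 adjusted over the list alone, with C1qa (-4.89), Adgre1 (-2.47) and C1qb (-2.42) lower and Slc40a1 (0.86), the iron exporter ferroportin, higher. This limma camera call ended with the prefix covariate (adjusted p = 0.0963) and without WT3 (adjusted p = 0.0840). By camera in limma the HSC/MPP list (adjusted p = 0.350) and the eosinophil list (adjusted p = 0.134) did not pass. Of the HSC/MPP list 18 members were tested, and 3 rose and 1 fell over all genes, and 5 and 2 adjusted over the list alone. In limma's camera its test passed downward with the prefix covariate (adjusted p = 0.0430). Of the 8 eosinophil genes tested, Ear2 (-1.92) and Ccr3 (-1.18) fell, 2 over all genes and 2 adjusted over the list alone; Ear2 has near-identical relatives, so its counts are uncertain. The list of stroma and endothelium and that of sex-linked genes had under 5 tested members and were not tested.

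The list of MHC class II genes fell (limma camera, adjusted p = 3.18e-07, 0.194 with estimated correlation). Of the 8 members 6 fell over all genes and 8 adjusted over the list alone, with H2-Eb1 (-0.85), H2-Aa (-0.81), H2-Ab1 (-0.72) and Cd74 (-0.71), which present antigen to helper T cells. The list of immediate early and dissociation stress genes fell (limma camera, adjusted p = 0.00552, 0.194 with estimated correlation). Of the 15 members 4 fell over all genes and 7 adjusted over the list alone, with Nr4a1 (-1.77), Jund (-0.74), Klf6 (-0.40) and Junb (-0.35), and its call ended with the prefix covariate (adjusted p = 0.136). The list of G2/M phase genes fell (limma camera, adjusted p = 0.0357, 0.596 with estimated correlation). Of the 22 members 1 fell over all genes and 1 adjusted over the list alone, the kinesin Kif23 (-0.74). This limma camera call ended with the prefix covariate (adjusted p = 0.996) and without KO1 (adjusted p = 0.0669), without KO2 (adjusted p = 0.131) and without WT3 (adjusted p = 0.314). Lineage transcription factors did not pass as a list (limma camera, adjusted p = 0.876), and members went both ways. Of 28, 8 rose and 6 fell over all genes, and 11 and 8 adjusted over the list alone. Erg (0.53), Runx1 (0.52), Meis1 (0.45) and Nfe2 (0.38) rose, factors of stem cells and of the megakaryocyte branch, and Id2 (-0.71) and Cebpb (-0.51) fell. The cohesin list did not pass (limma camera, adjusted p = 0.594), with Stag1 higher and Stag2 lower as its called members, over all genes and adjusted over the list alone. Its test and median (0.08) and mean (0.00390) were above 0.

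The lists of the interferon response (limma camera, adjusted p = 0.161), S phase (adjusted p = 0.685), p53 targets (adjusted p = 0.216) and haem synthesis (adjusted p = 0.216) did not pass. By limma's camera neither did HoxA and Meis genes (adjusted p = 0.974) nor mitochondrially encoded genes (adjusted p = 0.876). Called over all genes were Usp18 (-1.03) of 23 interferon genes, none of 22 S phase genes, Cdkn1a (-0.88) of 11 p53 targets, Alad (-0.33) of 10 haem genes, Meis1 of 10 HoxA and Meis genes and none of 13 mitochondrial genes. Adjusted over the list alone the counts were 1, 0, 1, 3, 1 and 0 in the same order. The HoxA and Meis list tested upward while its median (-0.13) and mean (-0.05) were below 0, and the mitochondrial list tested upward with a median of -0.00380 and a mean of 0.00330. With a correlation estimated from the data, none of the 16 lists past 0.05 kept its call (lowest adjusted p = 0.125 in limma's camera, 3 lists at unadjusted p under 0.05).

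Neutrophil granule transcripts were also higher in knockout cells of classes outside the neutrophil branch. Camp, Ngp, S100a8 and S100a9 together made up 211 ± 84.1 against 57.3 ± 38.6 CPM (SD, n = 3 each, knockout against wild type) in HSC/MPP, 245 ± 105 against 71.4 ± 46.5 in T/NK cells, 270 ± 102 against 72.7 ± 55.4 in basophil/mast cells and 259 ± 110 against 67.6 ± 55.7 in dendritic cells. They made up 197 ± 78.1 against 56.8 ± 38.3 CPM in early erythroid cells, 215 ± 101 against 53.4 ± 43.4 in lymphoid progenitors and 199 ± 85.5 against 61.8 ± 26.3 in megakaryocytes. Over all cells of each sample the same 4 genes made up 7011, 7075 and 4388 CPM in KO1, KO2 and KO3 and 836, 808 and 2456 CPM in WT1, WT2 and WT3. Among the largest rises on the log2 scale were Camp (2.10), Ngp (2.32), S100a8 (1.49) and S100a9 (1.69) in HSC/MPP, Ngp (2.37) in T/NK cells, Camp (2.34), Ngp (2.23) and S100a9 (1.66) in basophil/mast cells and Camp (2.13), S100a8 (1.75) and S100a9 (2.0) in dendritic cells. They were Camp (2.19) and Ngp (2.07) in early erythroid cells, Camp (2.80) and S100a9 (1.85) in lymphoid progenitors, S100a8 (1.70) and S100a9 (1.64) in megakaryocytes and Camp (2.55), Ngp (3.05) and S100a9 (2.57) in monocytes. edgeR adjusted p for these calls ran from 2.42e-04 (Camp, basophil/mast cells) to 0.0265 (S100a9, lymphoid progenitors). The late neutrophil list rose in HSC/MPP (limma camera, adjusted p = 5.83e-18, 0.0700 with estimated correlation), T/NK cells (adjusted p = 4.42e-11, 0.149 with estimated correlation), basophil/mast cells (adjusted p = 3.25e-07, 0.217 with estimated correlation) and dendritic cells (adjusted p = 2.17e-09, 0.161 with estimated correlation). It rose in early erythroid cells (adjusted p = 1.20e-08, 0.209 with estimated correlation) and monocytes (adjusted p = 2.81e-15, 0.297 with estimated correlation) too.

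Transcripts of other abundant cells stood at like low levels in unrelated classes. In CPM, knockout against wild type, Elane, a neutrophil protease, was 172 against 106 in T/NK cells, 169 against 94.8 in dendritic cells and 138 against 81.7 in early erythroid cells, beside 18093 against 21263 in granulocyte progenitors. Mcpt8, a basophil protease, was 111 against 219 in HSC/MPP, 105 against 266 in T/NK cells, 103 against 237 in dendritic cells and 105 against 206 in early erythroid cells, Ccl5 12 against 63.7 in early erythroid cells, 14.2 against 58.4 in granulocyte progenitors and 14.4 against 141 in dendritic cells beside 8449 against 13608 in T/NK cells, and Igkc 123 against 285 in HSC/MPP and 169 against 427 in T/NK cells. The granulocyte progenitor list rose in early erythroid (limma camera, adjusted p = 1.87e-06, 0.209 with estimated correlation), dendritic (adjusted p = 1.52e-06, 0.257 with estimated correlation) and T/NK cells (adjusted p = 3.41e-04, 0.458 with estimated correlation) at such levels. The plasma cell list fell likewise in HSC/MPP (limma camera, adjusted p = 1.80e-07, 0.0822 with estimated correlation, with 3 of 5 members past over all genes and 5 over the list alone), lymphoid progenitors (adjusted p = 1.50e-06, 0.0772 with estimated correlation), T/NK (adjusted p = 0.00235, 0.254 with estimated correlation) and basophil/mast cells (adjusted p = 0.00413, 0.217 with estimated correlation). None of these is set down to the cells themselves.

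Several of the granule gene calls rest on the tool or the library. DESeq2 ended the calls of Ngp (0.0763), Camp (0.0620), S100a9 (0.372) and S100a8 (0.377) in HSC/MPP, Ngp (0.0845) and S100a9 (0.0954) in basophil/mast cells, Camp (0.0986), S100a9 (0.192) and S100a8 (0.252) in dendritic cells, Camp (0.0565) and Ngp (0.0783) in early erythroid cells, S100a9 (0.637) in lymphoid progenitors, S100a9 (0.0918) in megakaryocytes, S100a9 (0.130) in monocytes (adjusted p in parentheses). The prefix covariate in edgeR ended the calls of Ngp (0.127), Camp (0.263) and S100a9 (0.0675) in HSC/MPP, Ngp (0.122) in T/NK cells, Camp (0.0507) in dendritic cells, Ngp (0.155) in early erythroid cells, Camp (0.0752) and S100a9 (0.285) in lymphoid progenitors, S100a8 (0.538) and S100a9 (0.303) in megakaryocytes, Ngp (0.195), S100a9 (0.195) and Camp (0.141) in monocytes. In edgeR, without KO1 the calls of S100a9 (0.0838) in lymphoid progenitors, without KO2 those of Ngp (0.0628) in T/NK cells, S100a9 (0.199) in lymphoid progenitors, S100a9 (0.103) in megakaryocytes, without WT2 those of Ngp (0.0671) and S100a9 (0.0836) in HSC/MPP, Camp (0.0612) in dendritic cells, Ngp (0.0533) in early erythroid cells, S100a9 (0.180) in lymphoid progenitors, S100a8 (0.160) and S100a9 (0.356) in megakaryocytes, S100a9 (0.0688) in monocytes ended. S100a9 also lost its call in basophil/mast cells when all deposited cells were used (1.08, edgeR adjusted p = 0.184), and in lymphoid progenitors and megakaryocytes with classes from resolution 2.0 (0.0513 and 0.0537). WT3, the wild type sample with the most granule transcripts, lowered several folds.

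**Figure D3:**
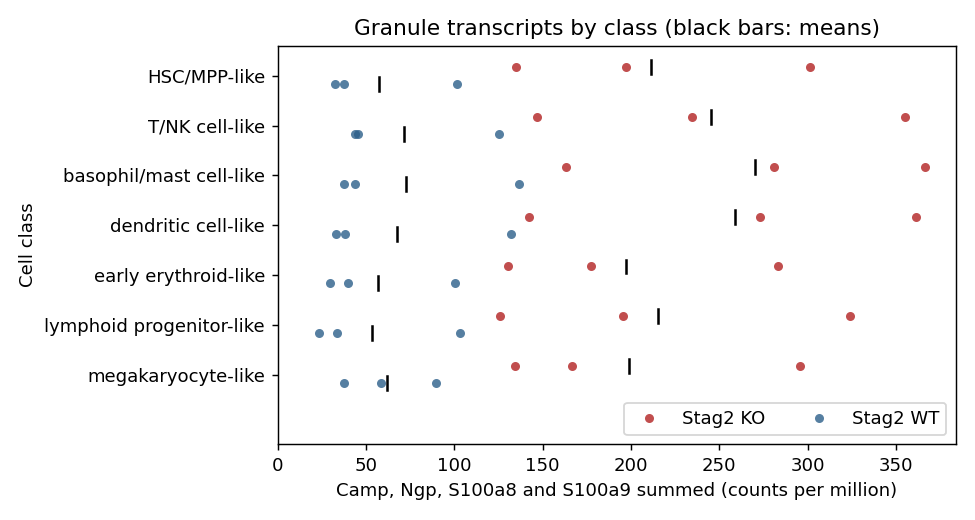
Camp, Ngp, S100a8 and S100a9 summed, in CPM, in each class outside the neutrophil branch, with a point per sample (red knockout, blue wild type, n = 3 each) and a black bar at each group mean. Knockout samples lie above all wild type samples of the same class, with means from 197 to 270 CPM against 53.4 to 72.7 CPM.

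Basophil/mast cell-like cells, the class with the most cells, changed in many genes at a like share of the sample. Ifitm1 fell from 3736 ± 351 to 232 ± 27.5 CPM (SD, n = 3 each), a log2 fold change of -4.00 ± 0.10 (edgeR adjusted p = 1.25e-13). Defb40 (-5.09), a beta-defensin, Igfbp7 (-4.60), Ms4a6c (-4.04), a membrane protein of the MS4A family, and Perp (-3.71), a p53 target of cell junctions, fell by more than 3 on the log2 scale, with edgeR adjusted p between 9.42e-13 and 2.85e-09. Nxpe2 (2.89, 19.0 against 4.04 CPM, edgeR adjusted p = 0.00206) and Mgst1 (2.10, 3.37e-05), a microsomal glutathione transferase, rose beside the granule genes. Basophil/mast cell markers fell (limma camera, adjusted p = 1.95e-06, 0.130 with estimated correlation): of 11 members 1 rose and 7 fell over all genes, and 1 and 7 adjusted over the list alone. Lower were Fcer1a (-1.41), Mcpt8 (-1.18), Hdc (-0.96) and Prss34 (-0.80), Hdc being the enzyme that makes histamine, and Il1rl1 (1.39) was higher. G2/M phase genes fell (limma camera, adjusted p = 1.70e-11, 0.217 with estimated correlation). Of the 22 members 17 fell over all genes and 20 adjusted over the list alone, with Ccnb1 (-0.80), Ube2c (-0.77), Cdk1 (-0.74) and Top2a (-0.47), genes of mitotic entry and exit. S phase genes fell (limma camera, adjusted p = 0.00249, 0.217 with estimated correlation). Of the 22 members 7 fell over all genes and 9 adjusted over the list alone, with Rrm2 (-0.82), a subunit of ribonucleotide reductase. Cluster 22 of this class, led by Mxd3 and histone genes beside basophil proteases, held 2.02% of wild type and 1.07% of knockout cells, so the makeup of the class moved with these lists.

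In the same cells megakaryocyte genes rose (limma camera, adjusted p = 0.00500, 0.217 with estimated correlation): of 9 members 2 rose and 0 fell over all genes, and 4 and 1 adjusted over the list alone, with Itgb3 (1.13) and Serpine2 (1.07). Monocyte genes fell (limma camera, adjusted p = 7.84e-06, 0.217 with estimated correlation): of 12 members 2 rose and 2 fell over all genes, and 2 and 4 adjusted over the list alone, with Slpi (-2.47) lower but F13a1 (1.42) and Ccr2 (0.72) higher. The HSC/MPP list fell (limma camera, adjusted p = 0.00500, 0.217 with estimated correlation): of 9 members 2 rose and 2 fell over all genes, and 3 and 3 adjusted over the list alone. Its median (0.24) was above 0 while its mean (-0.14) and its test were below. Klf1 fell by 0.97 on the log2 scale (edgeR adjusted p = 0.0128). Lineage transcription factors moved both ways (limma camera, adjusted p = 0.336), with Cebpe (1.78), Erg (1.24), Runx1 (0.86) and Meis1 (0.63) higher and Cebpb (-0.83) and Id2 (-0.77) lower.

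Different clusters held the basophil/mast cells of the genotypes: clusters 2 and 11 held 91.1%, 91.7% and 90.3% of those of KO1, KO2 and KO3, and 5.87%, 4.79% and 5.64% of those of WT1, WT2 and WT3, most of which lay in clusters 0 and 9. Of the lists, 11 of 23 passed in limma's camera, none with an estimated correlation (lowest adjusted p = 0.130, 3 at unadjusted p under 0.05). edgeR called 1239 of 9799 genes, 437 higher and 802 lower, 1202 of them without overlap between genotypes (30.013% of tested genes did not overlap). Calls numbered 392 with the prefix covariate, 353 of them shared, and edgeR made 813 without KO1 and 805 without WT2. The prefix covariate moved Nxpe2 to 0.76 (edgeR adjusted p = 0.231), and DESeq2 ended its call (adjusted p = 0.508). Defb40 stood at -5.80 without KO2, Nxpe2 at 5.52 without WT1, Nxpe2 at 2.28 without WT2 and Nxpe2 at 2.17, Camp at 3.15, Ngp at 3.70 and S100a9 at 2.54 without WT3 (log2 scale).

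**Figure D4:**
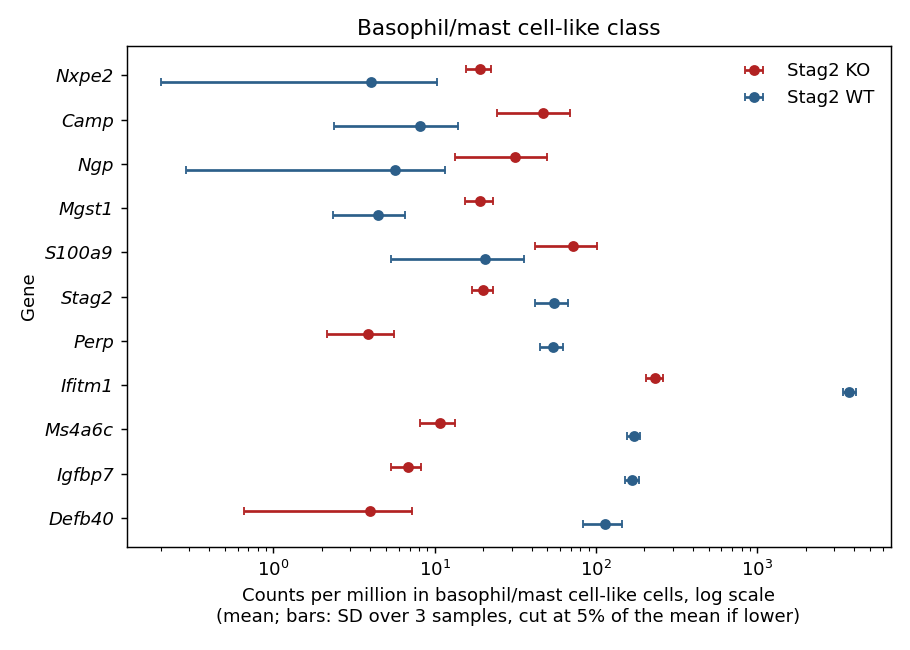
Level of the named genes in basophil/mast cell-like cells, in CPM on a log axis, as the mean of 3 knockout (red) and 3 wild type samples (blue), with SD as bars (drawn down to 5% of the mean where the SD reaches lower). Ifitm1 stands at 232 against 3736 CPM and Defb40 at 3.97 against 114 CPM.

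Early erythroid-like cells of the knockout samples had lower erythroid and higher megakaryocyte transcripts. Cd24a, a surface glycoprotein of maturing blood cells, fell from 223 ± 39.1 to 42.5 ± 16.0 CPM (SD, n = 3 each, -2.33 ± 0.18, edgeR adjusted p = 3.14e-07), and Mt2 from 243 ± 64.4 to 38.5 ± 23.1 CPM (-2.55 ± 0.25, edgeR adjusted p = 3.32e-06). Gna14 (-2.69), a G protein subunit, Gstp1 (-2.52), a glutathione transferase with a near-identical copy, and the chemokine Ccl5 (-2.64) fell too. Clec2i (2.06), a C-type lectin, and Tbc1d4 (1.78), which regulates glucose transporter traffic, rose, with edgeR adjusted p for these 5 genes between 3.55e-06 and 5.24e-04. Early erythroid genes fell (limma camera, adjusted p = 1.01e-20, 0.0984 with estimated correlation): of 18 members 2 rose and 14 fell over all genes, and 3 and 15 adjusted over the list alone, with Rhd (-1.83), Atp1b2 (-1.75), Aqp1 (-1.13) and Epor (-0.55) lower and Muc13 (0.56) and Zfpm1 (0.52) higher. Late erythroid genes fell (limma camera, adjusted p = 4.70e-07, 0.209 with estimated correlation). Of the 13 members 5 fell over all genes and 6 adjusted over the list alone, with Hba-a1 (-2.14) and Tfrc (-0.87), Tfrc being the transferrin receptor. Haem synthesis genes fell (limma camera, adjusted p = 2.01e-08, 0.209 with estimated correlation). Of the 9 members 5 fell over all genes and 8 adjusted over the list alone, with Cpox (-0.94), Alad (-0.75) and Urod (-0.66). Megakaryocyte genes rose (limma camera, adjusted p = 2.64e-15, 0.0504 with estimated correlation). Of the 12 members 9 rose over all genes and 9 adjusted over the list alone, with Plek (1.57), Gp5 (1.28), Gp9 (1.24) and Pf4 (1.16). Klf1 fell by 0.48 on the log2 scale (163 against 226 CPM, edgeR adjusted p = 0.00932) and Gata1 did not pass (-0.32, 0.0991).

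G2/M phase genes of early erythroid cells rose (limma camera, adjusted p = 4.69e-04, 0.248 with estimated correlation): of 22 members 6 rose and 1 fell over all genes, and 8 and 1 adjusted over the list alone, with Mki67 (0.85) and Top2a (0.70) higher and Cenpa (-0.66) lower. The class held cluster 28, led by haemoglobin genes, at 0.839% of wild type and 0.255% of knockout cells, and cluster 23, led by the platelet genes Pf4 and Gp1bb and by Car1, at 0.846% and 1.48%. Of the lists, 11 of 20 passed in limma's camera, none with an estimated correlation (lowest adjusted p = 0.0504, 3 at unadjusted p under 0.05). edgeR called 603 of 8655 genes, 269 higher and 334 lower, 580 of them without overlap between genotypes (25.6% of tested genes did not overlap). Calls numbered 200 with the prefix covariate, 167 of them shared, and edgeR made 392 without KO3 and 321 without WT3. Tbc1d4 (adjusted p = 0.181) lost the call in edgeR with the prefix covariate. Mt2 stood at -3.15 without KO1, Ccl5 at -3.25 without KO2 and Camp at 3.43 and Ngp at 2.82 without WT3 (log2 scale).

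HSC/MPP-like cells had lower transcripts of lymphoid, dendritic and monocyte genes in the knockout samples. Wfdc17, a WAP domain protein of myeloid cells, fell from 209 ± 27.0 to 28.8 ± 5.75 CPM (SD, n = 3 each, -2.88 ± 0.14, edgeR adjusted p = 3.99e-11). Slpi (-2.49), the secretory leukocyte protease inhibitor, Paqr5 (-2.23), a membrane progestin receptor, Shisa8 (-2.19) and Gstp1 (-1.98) fell as well, while Pde4d rose (1.56, 59.2 against 19.2 CPM), with edgeR adjusted p between 7.36e-07 and 2.24e-05. Lymphoid progenitor genes fell (limma camera, adjusted p = 5.27e-10, 0.0700 with estimated correlation). Of 9 members 0 rose and 4 fell over all genes, and 1 and 7 adjusted over the list alone, with Ly6d (-1.28), Flt3 (-1.17), Dntt (-0.89) and Lsp1 (-0.79). Monocyte genes fell (limma camera, adjusted p = 4.63e-15, 0.0700 with estimated correlation). Of the 7 members 4 fell over all genes and 5 adjusted over the list alone. HSC/MPP markers fell (limma camera, adjusted p = 2.58e-04, 0.206 with estimated correlation). Of the 15 members 4 fell over all genes and 6 adjusted over the list alone, with Ifitm1 (-1.20), Tcf15 (-0.97), Procr (-0.80) and Pdzk1ip1 (-0.76). Megakaryocyte genes rose (limma camera, adjusted p = 8.78e-05, 0.0822 with estimated correlation). Of the 8 members 2 rose over all genes and 5 adjusted over the list alone, with F2r (0.91) and Plek (0.52).

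In the same cells dendritic cell genes (limma camera, adjusted p = 3.05e-07, 0.0700 with estimated correlation) and MHC class II genes (adjusted p = 3.65e-09, 0.0822 with estimated correlation) fell, each with 5 members past over all genes and 5 adjusted over the list alone. Both calls ended in limma's camera with the prefix covariate (adjusted p = 0.0721 and 0.0923). Of the lists, 10 of 22 passed in limma's camera, none with an estimated correlation (lowest adjusted p = 0.0700, 8 at unadjusted p under 0.05). edgeR called 192 of 9617 genes, 46 higher and 146 lower, 183 of them without overlap between genotypes (16.1% of tested genes did not overlap). Calls numbered 78 with the prefix covariate, 56 of them shared, and edgeR made 123 without KO3. Gstp1 (adjusted p = 0.0574) lost the call in edgeR with the prefix covariate. Ngp stood at 3.17, S100a9 at 2.54 and S100a8 at 2.33 without WT3 (log2 scale).

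Granulocyte progenitor-like cells of the knockout samples carried more transcripts of later neutrophil stages. Chil3 (1.82, 74.9 against 17.1 CPM), Lcn2 (1.59), Siglece (2.33), an inhibitory sialic acid receptor, Hddc3 (1.96), a hydrolase, and Lect1 (1.76), chondromodulin, rose with edgeR adjusted p between 7.40e-07 and 1.30e-04. Slpi fell from 265 ± 15.5 to 67.1 ± 2.04 CPM (SD, n = 3 each, -1.98 ± 0.10, edgeR adjusted p = 1.33e-10). Ifitm1 (-2.77), Ccl5 (-2.38), Hist1h2ap (-2.14) and Gpc1 (-2.12), a heparan sulfate proteoglycan, fell too, with edgeR adjusted p between 1.53e-08 and 1.84e-04, Ifitm1 at 8.58 against 61.1 CPM beside 232 against 3736 CPM in basophil/mast cells. Late neutrophil genes rose (limma camera, adjusted p = 7.50e-14, 0.101 with estimated correlation). Of the 8 members 3 rose over all genes and 3 adjusted over the list alone, Lcn2, Chil3 and Wfdc21 (0.62). Monocyte genes fell (limma camera, adjusted p = 6.07e-09, 0.126 with estimated correlation): of 10 members 0 rose and 2 fell over all genes, and 1 and 3 adjusted over the list alone, with Ly6c2 (-1.15) beside Slpi. T/NK cell genes fell (limma camera, adjusted p = 1.18e-08, 0.126 with estimated correlation), at low levels: Cd3g stood at 0.351 against 4.40 CPM, and 2 of 5 members fell over all genes and 4 adjusted over the list alone.

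In granulocyte progenitors 8 of 22 lists passed in limma's camera, none with an estimated correlation (lowest adjusted p = 0.101, 5 at unadjusted p under 0.05). Without KO1 5 lists passed. edgeR called 186 of 9209 genes, 53 higher and 133 lower, 174 of them without overlap between genotypes (16.6% of tested genes did not overlap). Calls numbered 40 with the prefix covariate, 31 of them shared, and edgeR made 107 without KO1, 97 without KO3 and 69 without WT3. Hddc3, Lect1 and Ccl5 lost the call in edgeR with the prefix covariate and Ccl5 (adjusted p = 0.248) with DESeq2. Ccl5 stood at -3.10 without KO2 (log2 scale). Chil3 with the prefix covariate stood at 3.53 on the log2 scale.

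Monocyte-like cells of the knockout samples held more granulocyte transcripts. Fcnb (3.42, 46.3 against 4.49 CPM) and Lcn2 (3.21) rose beside the granule genes (edgeR adjusted p = 3.12e-04 and 0.00289). Ifitm1 fell from 77.8 ± 6.90 to 8.87 ± 2.37 CPM (SD, n = 3 each, -3.08 ± 0.21, edgeR adjusted p = 1.36e-06), beside 232 against 3736 CPM in basophil/mast cells. Cnn3 (-4.43), Pltp (-3.61), the phospholipid transfer protein, Slamf9 (-3.22), a receptor of the SLAM family, and Clec4b1 (-2.86), a C-type lectin, fell with edgeR adjusted p between 2.30e-05 and 4.43e-04. Genes of granulocyte progenitors rose (limma camera, adjusted p = 6.77e-05, 0.338 with estimated correlation). Of the 11 members 4 rose over all genes and 4 adjusted over the list alone, with Cebpe (2.67), at 15.7 against 2.51 CPM beside 338 against 316 CPM in granulocyte progenitors. S phase genes fell (limma camera, adjusted p = 9.46e-08, 0.155 with estimated correlation). Of the 22 members 6 fell over all genes and 11 adjusted over the list alone, with Rrm2 (-0.72) and Mcm3 (-0.64). G2/M phase genes fell (limma camera, adjusted p = 2.33e-05, 0.321 with estimated correlation). Of the 18 members 1 fell over all genes and 2 adjusted over the list alone, with Kif23 (-1.01).

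MHC class II genes fell in monocytes (limma camera, adjusted p = 2.94e-04, 0.321 with estimated correlation), with H2-Ab1 (-1.63) and Cd74 (-1.23), 3 of 7 members over all genes and 5 adjusted over the list alone, and the call ended with the prefix covariate (adjusted p = 0.526). Cluster 14, led by Ear2, Fcgr4 and Ace, held 4.73% of wild type and 1.18% of knockout cells, and cluster 26, led by Lyz2, Tgfbi and Fn1, held 0.438% and 1.66%, so the class differed in its parts. Of the lists, 7 of 16 passed in limma's camera, none with an estimated correlation (lowest adjusted p = 0.155, 2 at unadjusted p under 0.05). edgeR called 307 of 7553 genes, 120 higher and 187 lower, 300 of them without overlap between genotypes (21.4% of tested genes did not overlap). Calls numbered 35 with the prefix covariate, all shared, and edgeR made 161 without KO1, 144 without WT2 and 142 without WT3. Fcnb, Lcn2 and Slamf9 lost the call in edgeR with the prefix covariate. Lcn2 stood at 2.40, Ngp at 2.28, S100a9 at 1.52 and Cnn3 at -3.78 without KO2, Cnn3 at -6.55 without KO3 and Fcnb at 4.27, Lcn2 at 4.20, S100a9 at 3.44 and Camp at 3.24 without WT3 (log2 scale).

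Dendritic cell-like cells had lower transcripts of antigen presentation and of the cell cycle in the knockout samples. Cnn3 (-5.07, 0.994 against 36.4 CPM), Fn1 (-4.37), fibronectin, Fgl2 (-3.74), a fibrinogen-like protein, Ccl5 (-3.24) and Klk1b27 (-2.80), with near-identical relatives, fell with edgeR adjusted p between 5.91e-08 and 6.24e-04. Lysmd2 (2.0), a LysM domain protein, and Pgam2 (1.56), a phosphoglycerate mutase, rose beside the granule genes (edgeR adjusted p = 0.00736 and 0.00398). MHC class II genes fell (limma camera, adjusted p = 8.94e-11, 0.124 with estimated correlation). Of the 8 members 6 fell over all genes and 7 adjusted over the list alone. S phase genes fell (limma camera, adjusted p = 4.90e-12, 0.124 with estimated correlation). Of the 20 members 6 fell over all genes and 14 adjusted over the list alone, with Rrm2 (-1.44) and Dut (-0.82). G2/M phase genes fell (limma camera, adjusted p = 3.84e-10, 0.124 with estimated correlation). Of the 10 members 5 fell over all genes and 7 adjusted over the list alone, with Cdk1 (-1.55), Ccnb2 (-1.38) and Top2a (-1.12). Dendritic cell markers fell (limma camera, adjusted p = 0.0126, 0.257 with estimated correlation). Of 13 members 2 rose and 7 fell over all genes, and 4 and 7 adjusted over the list alone, with Batf3 (-1.04), Cox6a2 (-1.0) and Cd209a (-0.71) lower and Tcf4 (0.62) and Siglech (0.53), a factor and a receptor of plasmacytoid dendritic cells, higher. That call ended in limma's camera with the prefix covariate (adjusted p = 0.129) and without KO3 (adjusted p = 0.0757).

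Cluster 6, led by Siglech and Ly6d, held 5.81% of knockout and 3.92% of wild type cells, and cluster 13, led by MHC class II genes, 3.46% and 3.23%, so the makeup of the dendritic class differed as well. Id2, a factor of conventional dendritic cells, fell (-1.30). Of the lists, 8 of 18 passed in limma's camera, none with an estimated correlation (lowest adjusted p = 0.124, 4 at unadjusted p under 0.05). edgeR called 328 of 7679 genes, 110 higher and 218 lower, 313 of them without overlap between genotypes (21.5% of tested genes did not overlap). Calls numbered 125 with the prefix covariate, 105 of them shared, and edgeR made 198, 206 and 183 without KO1, KO2 and KO3 and 175 without WT3. Pgam2 (adjusted p = 0.167) lost the call in edgeR with the prefix covariate. Lysmd2 (adjusted p = 0.0512) lost the call in edgeR without KO2 and Lysmd2 (0.0554) without WT3. Fn1 stood at -4.98 and Ccl5 at -4.40 without KO2, Cnn3 at -6.30 and Fgl2 at -4.67 without KO3, Ccl5 at -2.31 without WT1, Lysmd2 at 2.86 without WT2 and Camp at 2.85, S100a9 at 3.02 and S100a8 at 2.77 without WT3 (log2 scale). Lysmd2 with the prefix covariate stood at 3.88 on the log2 scale.

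In T/NK cell-like cells members of the marker list went both ways. The CD3 chains Cd3d (-0.94), Cd3g (-0.90) and Cd3e (-0.87) and the T cell receptor chain Trbc2 (-0.86) fell, and the natural killer cell receptors Ncr1 (0.46) and Klrb1c (0.42) rose. Klrb1b, a natural killer cell receptor, rose from 30.4 ± 9.64 to 163 ± 14.1 CPM (SD, n = 3 each, 2.42 ± 0.17, edgeR adjusted p = 7.04e-07), and Tmem176a (2.30), a membrane channel of immune cells, Krt83 (3.96), a hair keratin, and Ccdc184 (5.16) rose with edgeR adjusted p between 2.55e-06 and 6.36e-04. Cym, the protease chymosin, fell from 50.7 ± 1.99 to 2.22 ± 1.36 CPM (-4.54 ± 0.31, edgeR adjusted p = 5.61e-07), and Ifitm1 (-2.52), Gstp1 (-1.87), Ddc (-1.70), which makes dopamine and serotonin, and Apoe (-1.63), apolipoprotein E, fell with edgeR adjusted p between 6.83e-04 and 0.0324. T/NK cell genes as a list fell (limma camera, adjusted p = 0.0200, 0.219 with estimated correlation). Of 13 members 2 rose and 4 fell over all genes, and 3 and 5 adjusted over the list alone, a call that ended with the prefix covariate (adjusted p = 0.207) and without KO3 (adjusted p = 0.0602). Clusters 8 (led by Trdc and Cd3d) and 19 (Cd8b1, Lef1, Ccr7) held 6.55% and 3.01% of wild type and 1.54% and 0.666% of knockout cells, while cluster 24, led by Klrb1b, Krt83 and Ncr1, held 0.701% and 1.64%, and cluster 5, led by Gzma and Klra4, 4.96% and 4.33%.

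In T/NK cells Ifitm1 stood at 7.56 against 41.4 CPM beside 232 against 3736 CPM in basophil/mast cells. Of the lists, 7 of 20 passed in limma's camera, none with an estimated correlation (lowest adjusted p = 0.149, 4 at unadjusted p under 0.05). edgeR called 197 of 7550 genes, 94 higher and 103 lower, 193 of them without overlap between genotypes (18.5% of tested genes did not overlap). Calls numbered 66 with the prefix covariate, 55 of them shared, and edgeR made 111 without KO1 and 103 without KO3. Ccdc184, Gstp1, Ddc and Apoe lost the call in edgeR with the prefix covariate and Ddc (adjusted p = 0.123) with DESeq2. Ddc (adjusted p = 0.201) and Apoe (0.202) lost the call in edgeR without KO1, Ddc (0.0684) and Apoe (0.0871) without KO2, Apoe (0.0856) without KO3, Ddc (0.0646) without WT2 and Ddc (0.131) and Apoe (0.0993) without WT3. Ngp stood at 1.59 without KO2, Ccdc184 at 6.12 without WT1 and Ccdc184 at 4.51 and Apoe at -0.99 without WT3 (log2 scale).

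Lymphoid progenitor-like cells had lower MHC class II and replication transcripts and higher granulocyte transcripts in the knockout samples. Cnn3 fell from 193 ± 28.6 to 23.1 ± 5.14 CPM (SD, n = 3 each, -3.04 ± 0.20, edgeR adjusted p = 8.01e-09), and Hist1h2ap (-2.96), Shisa8 (-2.67), Lgmn (-2.51), the lysosomal protease legumain, and H2-Aa (-2.11) fell with edgeR adjusted p between 9.78e-05 and 0.00259. Clec2i (1.83, 156 against 45.5 CPM), Hp (1.76), haptoglobin, and Rab38 (1.69), a GTPase of lysosome-related organelles, rose with edgeR adjusted p between 4.94e-05 and 0.0160. MHC class II genes fell (limma camera, adjusted p = 3.64e-11, 0.0772 with estimated correlation). Of the 6 members 4 fell over all genes and 5 adjusted over the list alone, with H2-Ab1 (-1.73) and Cd74 (-1.23). S phase genes fell (limma camera, adjusted p = 1.35e-11, 0.0772 with estimated correlation). Of the 22 members 4 fell over all genes and 9 adjusted over the list alone, with Rrm2 (-1.13) and Hells (-0.79). Dendritic cell genes fell (limma camera, adjusted p = 1.05e-05, 0.0772 with estimated correlation). Of 10 members 0 rose and 5 fell over all genes, and 2 and 5 adjusted over the list alone. Granulocyte progenitor genes rose (limma camera, adjusted p = 4.26e-05, 0.0772 with estimated correlation). Of 7 members 3 rose and 0 fell over all genes, and 4 and 1 adjusted over the list alone, with Mpo (1.13) at 510 against 234 CPM, beside 105 against 62.6 CPM in T/NK cells. Ebf1 did not pass within these cells (-0.45, 57.9 against 89.9 CPM, edgeR adjusted p = 0.742).

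Lymphoid progenitor markers themselves fell (limma camera, adjusted p = 0.0171, 0.206 with estimated correlation), with Il7r (-1.91) and Ly6d (-1.26) lower and Satb1 (0.64), a chromatin organiser, higher: 1 rose and 2 fell over all genes, and 1 and 3 adjusted over the list alone. The call ended in limma's camera with the prefix covariate (adjusted p = 0.0576) and without KO2 (adjusted p = 0.122), without KO3 (adjusted p = 0.0541) and without WT3 (adjusted p = 0.0517). G2/M phase genes fell (limma camera, adjusted p = 5.90e-04, 0.313 with estimated correlation), with Kif23 (-1.99) and Top2a (-0.62), a call that ended without KO1 (adjusted p = 0.0681). Of the lists, 7 of 16 passed in limma's camera, none with an estimated correlation (lowest adjusted p = 0.0772, 5 at unadjusted p under 0.05). edgeR called 110 of 6278 genes, 35 higher and 75 lower, 105 of them without overlap between genotypes (16.8% of tested genes did not overlap). Calls numbered 46 with the prefix covariate, 34 of them shared, and edgeR made 50 without KO1, 55 without KO3, 73 without WT2 and 45 without WT3. Hp (adjusted p = 0.298) and H2-Aa (0.189) lost the call in edgeR with the prefix covariate and Hp (0.129) and Rab38 (0.0533) with DESeq2. Hp (adjusted p = 0.250) lost the call in edgeR without KO1, Hp (0.0577) without KO2, Rab38 (0.0596) without KO3, Hp (0.103) without WT2 and Hp (0.0656) and Rab38 (0.0684) without WT3. Hist1h2ap stood at -3.62 without KO2 and S100a9 at 2.65 without WT3 (log2 scale). Clec2i stood at 1.17 and Rab38 at 2.61 with the prefix covariate on the log2 scale.

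Megakaryocyte-like cells, 23 to 141 cells per sample, differed in fewer genes. Fgf3, a fibroblast growth factor, rose (1.70 ± 0.25, 80.7 against 22.5 CPM, edgeR adjusted p = 2.75e-04), as did Smim1 (1.65), which carries the Vel blood group, and Pde4d (1.71). Gstp1 (-2.09), the glycolytic enzymes Pgk1 (-2.43) and Hk2 (-1.52) and the immunoglobulin genes Jchain (-1.96) and Igha (-1.55) fell, with edgeR adjusted p for these 7 genes between 2.75e-04 and 0.0484. Of 14 megakaryocyte markers tested, Vwf (-1.42), Serpine2 (-1.35) and Cavin2 (-0.71) fell over all genes, and 3 rose and 3 fell adjusted over the list alone, but the list did not pass (limma camera, adjusted p = 0.773). None of the 14 lists tested passed in limma's camera (lowest adjusted p = 0.0524, late erythroid), while 4 did at unadjusted p under 0.05, and 1 with an estimated correlation. Leaving out a library let 2 lists pass without KO1, 1 without KO3, 1 without WT1 and 2 without WT3. edgeR called 55 of 5617 genes, 18 higher and 37 lower, 50 of them without overlap between genotypes (14.9% of tested genes did not overlap). Calls numbered 17 with the prefix covariate, 9 of them shared, and edgeR made 26 without WT2 and 34 without WT3. Pde4d, Fgf3, Smim1, Pgk1, Gstp1, Jchain, Igha and Hk2 lost the call in edgeR with the prefix covariate. Smim1 (adjusted p = 0.14) lost it with DESeq2, Pde4d (0.0596) in edgeR on classes from resolution 2.0 and Pde4d (0.0504) in edgeR with RLE factors. Pde4d (adjusted p = 0.226), Pgk1 (0.0625) and Hk2 (0.0625) lost the call in edgeR without KO2, Pde4d (0.0941), Pgk1 (0.0742) and Jchain (0.0774) without KO3, Pde4d (0.0654) without WT1, Pde4d (0.252), Smim1 (0.103), Pgk1 (0.227) and Hk2 (0.0566) without WT2 and Pde4d (0.288), Pgk1 (0.0781), Jchain (0.648), Igha (0.208) and Hk2 (0.250) without WT3. S100a9 stood at 2.43 and Jchain at -0.91 without WT3 (log2 scale).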

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

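The tests of free RNA, of less complete removal and of the title code prefix, and the other splits behind the counts of changed genes, were chosen after the result was seen, as was the test of differences between classes.

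The knockout effect differed between classes in many genes, by limma on each sample's difference between a class and the others. It counted 691 genes (259 higher, 432 lower) for basophil/mast cells, 297 for early erythroid cells, 224 for T/NK cells, 171 for HSC/MPP, 152 for dendritic cells, 87 for monocytes, 21 for granulocyte progenitors, 16 for lymphoid progenitors and 6 for megakaryocytes. Leaving out a library moved some counts by over 1.5 times: early erythroid 195 without KO3 and 160 without WT3; T/NK 142 without WT2; HSC/MPP 82 without KO1, 103 without KO3 and 111 without WT3; dendritic 99 without KO1, 83 without KO2, 60 without KO3 and 99 without WT3; monocyte 44 without KO1, 144 without KO2, 57 without WT1, 137 without KO3, 28 without WT2 and 42 without WT3; granulocyte progenitor 9 without KO2 and 43 without WT1; lymphoid progenitor 32 without KO2, 8 without WT1, 9 without KO3, 5 without WT2 and 3 without WT3; megakaryocyte 2 without KO1, 3 without KO2, 15 without WT1, 3 without WT2 and 2 without WT3.

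Ifitm1 fell further in basophil/mast cells than in the other classes (-1.90 on the log2 scale, limma adjusted p = 3.85e-11), as did Stag2 (-0.64, 0.00423), and Spi1 was lower there relative to the others (-0.31, 8.49e-04). Cd24a (-2.01, limma adjusted p = 1.52e-10) and Gstp1 (-0.80, 0.00694) fell further in early erythroid cells, Slpi (-0.93, 0.0317) in HSC/MPP, and Tmem176a rose further in T/NK cells (2.13, 9.58e-09).

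Each count of changed genes came from 1 of 10 splits of the 6 samples, too few for a share under 0.05. By genotype edgeR called 1360 genes in all cells, 1239 in basophil/mast cells, 603 in early erythroid cells and 307 in monocytes, where the highest other split called 0. The highest other split called 16 genes in dendritic cells (328 by genotype), 10 in granulocyte progenitors (186), 3 in HSC/MPP (192), 2 in T/NK cells (197), 17 in lymphoid progenitors (110) and 18 in megakaryocytes (55), in each case KO1, WT2 and WT3 against the rest. For the differences between classes the highest other split called 3 genes in lymphoid progenitors, 1 in dendritic cells and 0 in the other classes.

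Camp, Ngp, S100a8 and S100a9 were higher in knockout cells outside the neutrophil branch. Doublets with a neutrophil would put these UMIs in few cells, but the 5% of cells with the most held a median of 19.3% of them, which argues against doublets as the main source; over knockout samples and classes it ran from 10.8% to 30%, and reached the 25% bound set beforehand in basophil/mast and dendritic cells of KO1 and T/NK cells of KO3. Free RNA from neutrophils may contribute: the 4 genes kept nearly the proportions they had in all cells of the sample (median absolute log2 difference 0.158), and the knockout samples held more of these transcripts in all. Expression by the knockout cells themselves stays open, since it was not tested apart from free RNA. Low levels of Elane, Mcpt8, Ccl5, Igha and Ifitm1 in unrelated classes may be free RNA too, by the like levels alone.

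Basophil/mast cells of the genotypes lay in separate clusters. A library batch that follows the prefix is argued against by WT1, which shares the prefix with the knockout samples and had 5.87% of these cells in the clusters of the knockout cells. Depth per cell is argued against by thinning to 2000 UMIs, after which 83.0% of nearest neighbours in other samples had the cell's genotype (86.9% unthinned, 40% with full mixing); WT1 alone stood at 71.5%, and 98, 28 and 59 cells of KO1, KO2 and KO3 and 101, 127 and 875 of WT1, WT2 and WT3 were too shallow. A change of state with genotype may account for the split, as a hypothesis, and batches other than the prefix stay open.

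B cells and T/NK cells had smaller shares in the knockout samples. A batch by prefix is argued against by the B cell share of WT1, 2.36%, near those of the other wild type samples. Less complete removal of mature cells from the wild type samples stays open: late neutrophils were 7.53-fold higher in the knockout samples (12.5-fold without WT3), but granulocyte progenitors rose too, and clusters 14 (1.18% of knockout and 4.73% of wild type cells) and 28 (0.255% and 0.839%) were lower. Depletion that differed for lymphoid cells alone, and an effect of genotype on lymphoid output, may each account for it too.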

How the results depend on the processing

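The tests of RLE factors and of left-out libraries for the differences between classes were chosen after the result was seen. Of 116 named gene results 64 kept direction and call in every alternative and 52 did not; the cause was not tested. DESeq2 ended 21 of 110 calls (6 more had no adjusted p), leaving out a library 51 of 696, resolution 2.0 3 of 90, and RLE factors and no cell filter 1 of 116 each, while no low-count filter ended 0 of 116. The same class shares in every sample ended 4 of 26 calls in all cells and turned S100a9 (-0.0672) and S100a8 (-0.15). Stag1 stood at 0.22 with the prefix covariate and at 0.25 to 0.35 without each library. Calls were made at class depths down to 222600 UMIs. No paired analysis was possible because the replicate numbers follow accession order.

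With the prefix covariate edgeR called 754 genes in all cells, 78 in HSC/MPP, 66 in T/NK cells, 392 in basophil/mast cells, 125 in dendritic cells, 200 in early erythroid cells, 40 in granulocyte progenitors, 46 in lymphoid progenitors, 17 in megakaryocytes and 35 in monocytes. DESeq2 called 117 in HSC/MPP, 118 in T/NK cells, 766 in basophil/mast cells, 154 in dendritic cells, 288 in early erythroid cells, 118 in granulocyte progenitors, 45 in lymphoid progenitors, 24 in megakaryocytes and 168 in monocytes. DESeq2 called 1295 in all cells, and its share of higher calls was 16.7% in megakaryocytes (32.7% in edgeR) and 25.6% in basophil/mast cells (35.3%). No low-count filter gave 349 in HSC/MPP, 378 in T/NK cells, 497 in dendritic cells, 359 in granulocyte progenitors, 183 in lymphoid progenitors, 100 in megakaryocytes and 574 in monocytes, and resolution 2.0 gave 569 in dendritic cells. Without each library edgeR called 748 to 1473 genes in all cells, 123 to 255 in HSC/MPP, 103 to 210 in T/NK cells, 805 to 1346 in basophil/mast cells, 175 to 371 in dendritic cells and 321 to 556 in early erythroid cells. It called 69 to 257 in granulocyte progenitors, 45 to 142 in lymphoid progenitors, 26 to 71 in megakaryocytes and 142 to 328 in monocytes. RLE factors and no cell filter kept each count within 1.5 times. With an estimated correlation limma's camera passed 0 lists in all cells (3 at unadjusted p under 0.05) and 0 in the 9 classes (1 in megakaryocytes to 8 in HSC/MPP unadjusted).

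edgeR on cell counts called shares of B cells (-4.37), HSC/MPP (0.60), T/NK cells (-0.82), granulocyte progenitors (1.29), late neutrophils (2.72), lymphoid progenitors (-0.59) and megakaryocytes (1.22, log2), which the exact test cannot. The difference in percentage points, knockout minus wild type, reversed for basophil/mast cells (-1.20) with cells of at least 2000 UMIs (1.75), marker scores (0.0072) and XA samples alone (1.10). It reversed for early erythroid cells (0.195) with at least 2000 UMIs (-0.686), marker scores (-0.177) and left-out libraries (-0.256 to 0.524, below 0 without KO1 or WT1), and for eosinophils (0.287) with marker scores (-0.530). Cluster 13 (0.230) reversed with XA samples alone (-0.147) and without WT3 (-0.0346 to 0.435). Cluster 5 (-0.624) reversed without KO3 (-1.06 to 0.0305), cluster 7 (0.143) without KO1 or WT1 (-0.248 to 0.402) and cluster 18 (-0.323) without WT1 (-1.06 to 0.734). None of these reversed shares had passed a test. Doublets kept and resolutions 0.5 and 2.0 reversed none, though resolution 0.5 gave no lymphoid progenitor or megakaryocyte class; doublets kept and at least 2000 UMIs were not run for clusters.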

Other observations

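A cluster left unnamed, led by Gata3, Icos, Ly6a and Arg1, held 2.0% ± 0.280 (SD, n = 3) of the knockout and 2.32% ± 1.88 of the wild type cells (exact permutation p = 1). Another, led by Mxd3, Kif23 and Hist1h2ap, held 1.55% ± 0.602 and 3.54% ± 0.620 (exact permutation p = 0.1, the smallest the design allows). Hist1h2ap itself was lower over all knockout cells, so the latter share is given as a value alone.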
